A study of Arachis hypogaea with 14 samples.

How the data were processed

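Small RNA libraries were made from seeds of the peanut lines 8106 and 8107, which the series' design text describes as recombinant inbred lines of the 8th generation with medium-sized pods (8106) and very large pods (8107), sampled 15 days and 35 days after flowering (DAF). The line, stage and replicate number of each of the 12 small RNA libraries came from the labels' characteristics, which give 4 groups of 3. A further 2 degradome libraries, 1 per line, carry both stages in their labels. The labels do not state whether replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, small RNA libraries were made with the TruSeq small RNA kit and sequenced as single reads of 50 bases, and degradome libraries capture fragments with a 5′ monophosphate. The submitters' processing notes name Bowtie, with no version and no role.

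The small RNA table holds a per-library signal that the authors deposited as normalized reads, per the file headers; the normalization method is not given in the sources used here. Within a library nearly all values were whole multiples of 1 step, 98.2 to 99.4% of them within a tolerance of 0.02 steps, so nearly all values of a library fit read counts times 1 factor. Dividing by the step gave totals of 580011 to 3243620 reads over the listed entries, which describe depth over the listed entries and entered only the voom alternative, not the main test. The lowest value above 0 stood for 6 reads in 11 of the 12 libraries and for 0.5 of a step in the other, so an entry listed at 0 may have had up to a few reads, and a listed 0 is not absence. The degradome table gives an alignment score for each small RNA and cleavage site, as the authors deposited it, per the file headers, from 0 to 4, where a lower score is a better match. It gives no library, cleavage category, p-value or abundance, so the part of the naming rule that rests on abundance could not be run, the pairs named were chosen by score after the table was seen, and a combination of small RNA, transcript and site could only be counted as listed 1 or 2 times, not assigned to a line.

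The small RNA table had 1082 lines for 795 different sequences, which were 273 known miRNA entries, 140 other arms of known hairpins and 382 predicted candidates. A prefix gives the species of the matched miRNA (ahy, peanut; gma, soybean; mtr, Medicago truncatula), R and L give bases added or removed at the 3′ and 5′ end, a number before ss gives substitutions, MIR with p5 or p3 marks a hairpin arm and PC a predicted candidate. In 36 sets, holding 79 sequences, all 12 values were identical, so reads shared between near-identical entries may count in each, and such entries are uncertain as separate molecules. Levels are given as mean ± SD of normalized reads over 3 libraries. No genome was used here, so positions of the loci are not given; none of the 1196 degradome transcripts matched the reference table of gene symbols, and symbols are those the authors' table gives.

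Before the data were examined, the groups, the tests, the lists, the rule for named entries and the other settings to try were fixed, with 1 test for counts and another for normalized values. Since the values were normalized, limma 3.58.1 in R 4.3.3 was run with a trend on log2(value + 1), over entries at 10 or more in at least 3 of the 12 libraries, with 1 mean per group and no replicate block, and Benjamini-Hochberg adjusted p under 0.05. This left 395 entries, of them 171 known, 66 hairpin arms and 158 predicted. The 5 comparisons were 8107 minus 8106 at each stage, 35 minus 15 DAF in each line, and the difference of the lines' stage changes. A fold change on the log2(value + 1) scale understates the change of low entries, and log2 differences are given ± SE. The rule named, per comparison, the 8 highest and 8 lowest log2 differences among known entries and the 4 and 4 among other entries that passed with groups that did not overlap, the 4 most abundant members of each list, the 10 most abundant entries, and for the difference of stage changes the 8 smallest p. Sums per family quoted here were chosen after their values were seen, as were entries outside the rule.

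The 10 lists of miRNA families, tested with limma's camera at a preset correlation of 0.01 with adjustment over 50 tests, were SPL and phase change, auxin signalling, growth and organ development, the small RNA pathway, copper and laccase, sulfur and phosphate nutrition, NB-LRR and phasiRNA triggers, legume families, families registered in Arachis, and conserved core families. The members overlap between lists. All 18 SPL, 19 auxin, 61 growth, 3 small RNA pathway, 15 NB-LRR and 118 conserved core members tested also stood in another list, as did 6 of 7 copper, 6 of 7 sulfur and phosphate, 10 of 26 legume and 0 of 6 Arachis members. Shares of the listed entries' reads by length were compared with a two-sided exact permutation test. On simulated libraries with the 6-read floor and the real entries' median spread (overdispersion 0.0282), the comparison at 15 DAF, run on 341 entries, recovered 92% of 50 entries changed 2-fold and 100% of 50 changed 4-fold, with 3 of 99 calls false; at a wider assumed spread of 0.08, on 344 entries, it recovered 42% and 100%, with 2 of 73 calls false. The median spread came only from entries averaging 100 or more reads in a group. The simulation held no deviation shared between libraries and no scaling shift, so its rates may not carry over to these libraries. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and, for duplex energies, ViennaRNA 2.7.2 were also used.

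Same-numbered libraries were checked for pairing by the correlation of their deviations from the group means over the tested entries. It was over 0.1 for every pair in the comparison at 15 DAF (0.148 to 0.542) and in the stage changes of 8106 (0.122 to 0.677) and 8107 (0.159 to 0.512), so by the rule set beforehand the numbers pair those samples, and not at 35 DAF (0.039 to 0.658). The 4 replicate 2 libraries deviated together (r = 0.512 to 0.677) and against all others (-0.652 to -0.106). Against the mean of replicates 1 and 3, their short sequences lay higher and their long ones lower. The median log2 deviation of 24 nt entries ran from -1.04 to -3.40 over the 4 groups. Deviations within a group sum to 0, so a shared replicate 2 deviation alone can make other same-numbered libraries correlate. In all, 8 libraries correlated best with 1 of their own number. Replicate 1 of 8106 at 15 DAF, however, correlated at 0.593 with replicate 3 at 35 DAF and at 0.320 with replicate 1. The rule therefore cannot tell pairing from a shared replicate 2 effect.

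Other settings chosen beforehand were limma without trend, quantile normalization, median centring, no filter, a minimum of 50, pseudocounts of 0.1 and 10, the replicate block, voom with sample quality weights, a 2-fold minimum, known entries alone, sums per family, the 6 libraries compared alone and each library left out; for lists an estimated correlation, fry, the block and hairpin arms included; and for the degradome a score of 2.5 or less and other units of overlap. After seeing the data, 8 were added: equal library totals, a common floor, identical values counted once, leaving out the 4 replicate 2 libraries, leaving out entries of miR6300, miR6478 and miR2916, families that resemble tRNA or rRNA fragments, degradome combinations counted as listed 2 times, length shares compared in pairs, and 3 more families among the target classes. Count tests were foreseen only for a table of counts and were not run on the step-divided values, which are not all whole and lack values under 6 reads. Degradome categories and p thresholds could not be run, since the table holds neither. Quantile normalization gives entries of equal rank equal values. ahy-miR167-5p ranked 1 in 11 of the 12 libraries, gma-miR482b-3p ranked 2 in 10 and mtr-miR166a ranked 2 to 4 in all, so their values under it follow from rank and are no evidence on their differences. The target classes of the degradome and its symbols for seed, hormone and cell wall genes were also chosen after the table had been seen.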

Results

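Small RNAs were sequenced from peanut (Arachis hypogaea) seeds of the medium-pod line 8106 and the large-pod line 8107 at 15 and 35 DAF, with 3 libraries in each of 4 groups, to ask which miRNAs differ between the lines and change as the seed grows. The 12 libraries held total normalized reads of 464658 to 1086380, from an estimated 580011 to 3243620 reads over the listed entries, and 36.0 to 54.5% of the 795 entries were listed at 0 in a library. The 2 most abundant entries of a library took 47.5 to 70.1% of its values. They were led by ahy-miR167-5p, of a family that targets auxin response factors, and gma-miR482b-3p, of a family that targets NB-LRR resistance genes. In the degradome these entries had 2 transcripts of MED12 and 1 transcript without a symbol, so the target classes are background.

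At 15 DAF, members of families that target copper proteins and laccases were higher in 8107 than in 8106. ahy-miR398_R+1, of a family that targets copper superoxide dismutases, stood at 788 ± 138 normalized reads in 8107 against 60.9 ± 10.2 in 8106 (mean ± SD, n = 3 libraries each), a log2 difference of 3.67 ± 0.33 (SE; limma adjusted p = 3.04e-05). mtr-miR397-5p, which targets laccases, stood at 152 ± 64.2 against 19.4 ± 3.25 (2.84 ± 0.31, adjusted p = 0.000119). ahy-miR3508, of a family registered in peanut, stood at 4428 ± 526 in 8107 and 328 ± 46.9 in 8106 (3.76 ± 0.21, adjusted p = 1.36e-06). Lower in 8107 were gma-miR159a-5p_2ss19TA20TA (229 ± 4.99 against 737 ± 31.9, log2 difference -1.69 ± 0.14) and gma-miR482b-3p (122306 ± 18676 against 189678 ± 22393, -0.64 ± 0.20), the last a call lost under equal library totals.

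The other members of the copper and laccase list were also higher in 8107 at 15 DAF. In the degradome table mtr-miR397-5p had 6 transcripts of PYRE-F and no laccase symbol, and ahy-miR398_R+1 had 3 of PBS1 and no superoxide dismutase symbol, so these target classes are background and not read from this table. mtr-miR398b differed by 1.79 ± 0.27, and ahy-miR408-3p, of a family that targets blue copper proteins, was listed at 30.9, 44.5 and 37.4 in the 3 libraries of 8107 and at 0, 6.23 and 10.5 in those of 8106, a call lost with median centring. gma-miR4376-5p_R-1_2ss16AG21GA, of a family known in tomato to target a calcium ATPase, differed by 1.02 ± 0.27, a call lost under quantile normalization and median centring. Of the miR156 family, which targets SPL transcription factors, mdm-miR156a_1ss11GA stood at 919 ± 179 against 202 ± 66.2 (2.21 ± 0.32), whereas the most abundant member, mtr-miR156e, stood at 1535 ± 181 and 1500.3 ± 229 and did not pass. Summed per family, miR319, which targets TCP factors, was higher in 8107 by 1.52 ± 0.29 and miR169, which targets NF-YA factors, lower (-0.76 ± 0.18), with 0.73 and -1.54 under median centring. The predicted candidate PC-3p-4234_1541 (TAATCCATATCCGAAGCACTCG) was listed at 0 in all 6 libraries of 8106 and stood at 347 ± 34.1 in 8107 at 15 DAF and 428 ± 55.3 at 35 DAF. PC-5p-34874_230 was likewise listed at 0 in 8106, at 38.9 ± 7.51 and 86.4 ± 35 in 8107.

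All 7 tested members of the copper and laccase list were higher in 8107 at 15 DAF, and also 7 adjusted over the list alone, with a median log2 difference of 3.13 (camera adjusted p = 0.000377). That call was lost at adjusted p = 0.934 with an estimated correlation, and 2 of the 7, forms of miR408, share the same values. No other list passed at 15 DAF, and members overlap between lists. The SPL and phase change list had 3 higher, 1 lower and 14 not passed, the auxin signalling list 2 higher, 1 lower and 16 not passed, the growth and organ development list 16 higher, 3 lower and 42 not passed, and the small RNA pathway list 0 higher, 0 lower and 3 not passed. The sulfur and phosphate list had 0 higher, 1 lower and 6 not passed, the NB-LRR and phasiRNA list 1 higher, 2 lower and 12 not passed, the legume list 1 higher, 0 lower and 25 not passed, the Arachis list 2 higher, 0 lower and 4 not passed, and the conserved core list 28 higher, 8 lower and 82 not passed. Higher and lower counts adjusted over the list alone differed from these for growth (18 and 4), legume (0 and 0) and conserved core (30 and 9). The list splits depend on the scaling. With median centring growth had 5 higher and 4 lower and conserved core 12 and 9. With quantile normalization these were 10 and 4, and 21 and 11. The majority turned for auxin, to 1 higher and 3 lower with quantile normalization and 0 and 1 with median centring. It also turned for legume, to 1 and 2, and 0 and 1. The median, mean and test differed in sign for the sulfur and phosphate, legume and Arachis lists.

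Of 395 tested entries, 89 passed at 15 DAF, 62 higher in 8107 and 27 lower, and 174 (44.1%) had groups that did not overlap, where chance gives 10%. Of 16 tested entries that resemble tRNA or rRNA fragments, 7 were higher and 0 lower. The share of higher calls, 69.7%, was 41% with median centring (25 higher and 36 lower) and 52.4% with quantile normalization (43 and 39). These 2 scalings moved the median of all entries from -0.09 to -0.34 and -0.16, and the count was 145 with the replicate number as a block and 170 with voom and sample quality weights. It fell to 42 without replicate 1 of 8106, 47 without its replicate 3, and to 51 and 52 without replicates 2 and 3 of 8107.

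**Figure D1:**
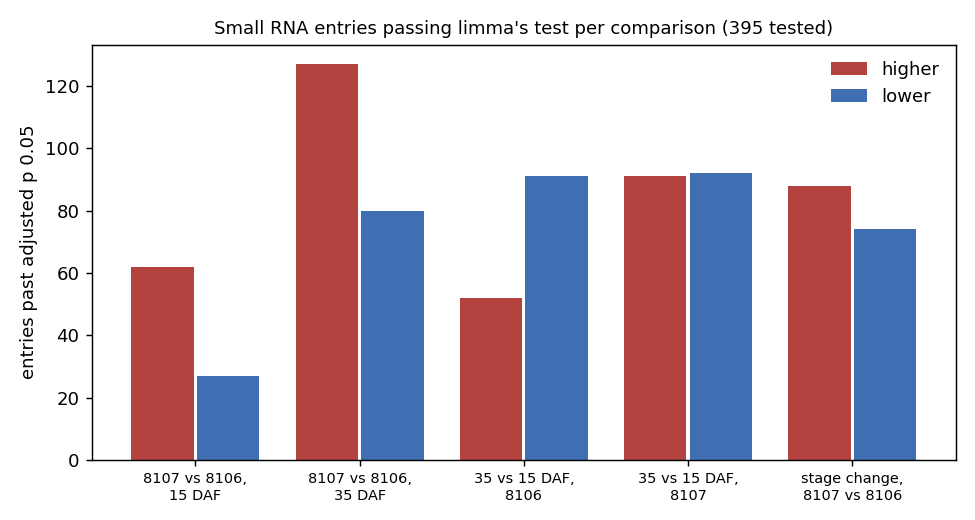
Numbers of entries, of 395 tested, that passed limma at adjusted p under 0.05 in each of the 5 comparisons, as bars for higher and lower entries on a linear axis. The counts were 62 higher and 27 lower between lines at 15 DAF, 127 and 80 at 35 DAF, 52 and 91 from 15 to 35 DAF in 8106, 91 and 92 in 8107, and 88 and 74 for the difference of the stage changes, and the split at 35 DAF turned to 93 and 110 with median centring.

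At 35 DAF, ahy-miR167-3p_L-1, from the opposite strand of the miR167 duplex, was higher in 8107, at 8059.7 ± 885 against 386 ± 82.8 in 8106 (n = 3 each; 4.40 ± 0.16, limma adjusted p = 5.24e-09). mdm-miR156a_1ss11GA stood at 2769.5 ± 994 against 30.1 ± 10.5 (6.47 ± 0.32). Summed per family, however, miR156 did not pass, at 10150 against 8520 (0.27 ± 0.25, limma adjusted p = 0.361). Another isoform, ppe-miR156a_R+1_1ss5AG, was lower in 8107 (-2.04). mtr-miR319a-3p_R+1_2, of a family that targets TCP factors, stood at 2312 ± 791 against 50.4 ± 19.6 (5.51 ± 0.30). The miR319 sum differed far less, at 6166 against 3818 (0.73 ± 0.29, limma adjusted p = 0.0358). mtr-miR164a, which targets NAC factors, was lower at 1124 ± 216 against 5671 ± 1413 (-2.32 ± 0.22, adjusted p = 8.25e-06), and gma-miR482b-3p at 52357 ± 8644 against 270216 ± 46327 (-2.37 ± 0.20). With equal totals these were -1.27 and -1.31.

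The mature ahy-miR167-5p was lower in 8107 at 35 DAF (186348 ± 15771 against 433359 ± 50717, -1.21 ± 0.14), and that call was lost with equal library totals (-0.16). mtr-miR160a, which also targets auxin response factors, was lower (-0.98 ± 0.21), but was 0.07 with equal totals. mtr-miR172d-3p_R+1, of a family that targets AP2-like factors, was higher in 8107 at 2832 ± 437 against 946 ± 106 (1.58 ± 0.14, 2.63 with equal totals and 0.97 with quantile normalization). mtr-miR395a_L+1R-1_1ss21TC, of a family that targets ATP sulfurylase, stood at 196 ± 51.1 against 37.7 ± 5.92. Summed per family, miR390, which triggers small RNAs against auxin response factors, was higher by 2.95 ± 0.22, miR393, which targets auxin receptors, by 2.13 ± 0.32, and miR396, which targets growth-regulating factors, by 1.47 ± 0.19 (2.52 with equal totals). The miR393 call was lost with quantile normalization (0.50). miR171, which targets SCARECROW-like factors, was lower (-1.10 ± 0.20), a call lost with equal totals (-0.04). mtr-miR166a, of a family that targets HD-ZIP III factors, was lower (-0.47 ± 0.14) in the main scaling but 0.58 with equal totals. mtr-miR2199_1ss17AG stood at 226 ± 60.2 in 8107 and was listed at 0 in all 3 libraries of 8106.

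The SPL and phase change list had 12 higher, 1 lower and 5 not passed at 35 DAF (median 1.80, and 2.81 with equal totals), but no list passed by camera (SPL adjusted p = 0.0743). The auxin signalling list had 10 higher, 4 lower and 5 not passed, the growth list 22 higher, 20 lower and 19 not passed, the small RNA pathway list 0 higher, 1 lower and 2 not passed, and the copper and laccase list 1 higher, 1 lower and 5 not passed. The sulfur and phosphate list had 5 higher, 0 lower and 2 not passed, and the NB-LRR and phasiRNA list 3 higher, 6 lower and 6 not passed. The legume list had 4 higher, 12 lower and 10 not passed, the Arachis list 2 higher, 1 lower and 3 not passed, and the conserved core list 51 higher, 30 lower and 37 not passed. Counts of higher and lower members adjusted over the list alone differed for auxin (10 and 5), the small RNA pathway (0 and 2), copper (1 and 0) and conserved core (51 and 32). With equal totals growth had 39 higher and 7 lower, auxin 13 and 0, NB-LRR 3 and 3, legume 6 and 1 and conserved core 77 and 11. With quantile normalization growth had 14 and 23, auxin 6 and 6 and conserved core 35 and 35. With median centring these were 14 and 25, 8 and 7, and 38 and 42. Sulfur and phosphate had 3 and 0 with each of these 2. The signs of the growth list's median, mean and test differed.

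Of the 395 entries, 207 passed at 35 DAF, 127 higher and 80 lower in 8107 (137 with only the 6 libraries compared, 93 and 44), with 208 (52.7%) not overlapping. The fragment-like entries had 3 higher and 5 lower. The share of higher calls moved from 61.4% to 46.6% with quantile normalization (89 and 102), 45.8% with median centring (93 and 110), and 85.2% with equal totals (201 and 35). Scaling to equal totals moved the median of all entries from 0.03 to 1.08, and quantile normalization and median centring to -0.38 and -0.37, so differences smaller than these shifts can change direction with the scaling.

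**Figure D2:**
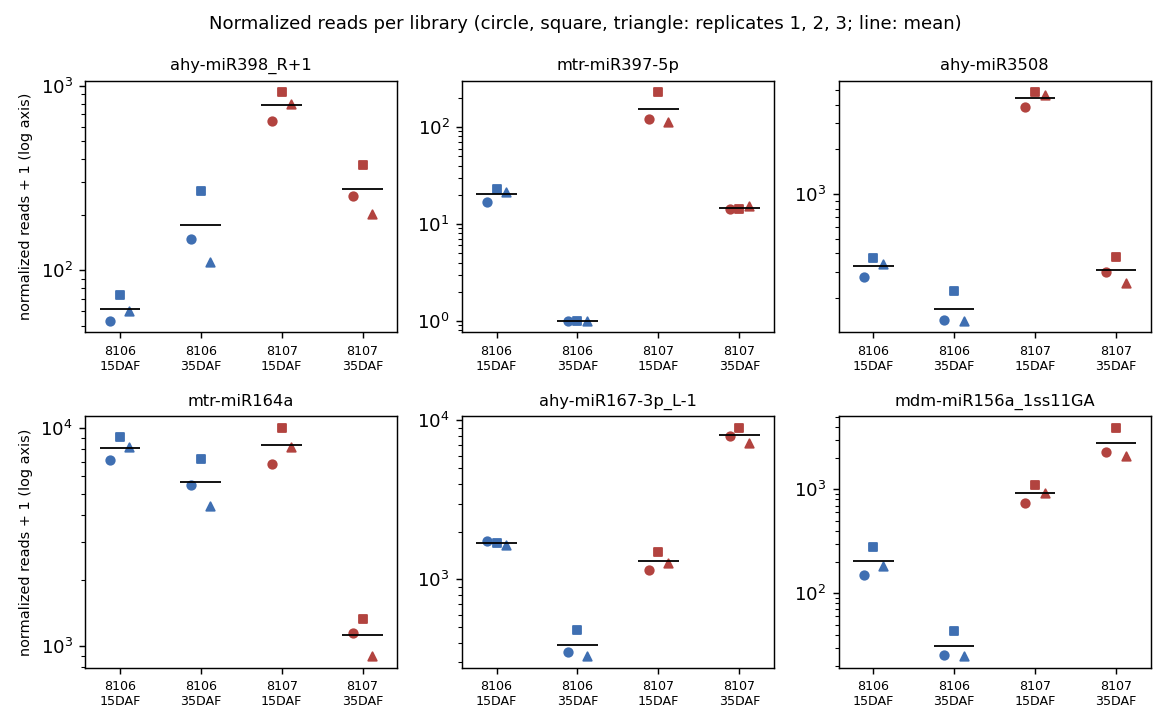
Normalized reads plus 1 on a log axis for 6 small RNAs in the 12 libraries, with the group mean as a bar and circles, squares and triangles for replicates 1, 2 and 3. ahy-miR398_R+1 stood at 60.9 and 788 at 15 DAF in 8106 and 8107, and mtr-miR164a at 5671 and 1124 at 35 DAF.

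In 8106, mtr-miR156e rose from 1500.3 ± 229 at 15 DAF to 7809 ± 2440.4 at 35 DAF (n = 3 each; 2.35 ± 0.22, limma adjusted p = 1.18e-05). mtr-miR172d-3p_R+1, whose family targets AP2-like factors, fell from 3149.9 ± 235 to 946 ± 106 (-1.74 ± 0.14, adjusted p = 4.95e-06). ahy-miR3518, registered in peanut, rose by 1.96 ± 0.14, and ahy-miR167-5p rose from 213076 ± 7963 to 433359 ± 50717 (1.02 ± 0.14, and 0.41 with equal totals). The passenger strand ahy-miR167-3p_L-1 fell (-2.15 ± 0.16). mtr-miR397-5p fell from 19.4 ± 3.25 to a group listed at 0 in all 3 libraries, and mtr-miR398b fell from 505 ± 64.3 to 167 ± 55.5 (-1.64 ± 0.27), while ahy-miR398_R+1 rose from 60.9 ± 10.2 to 175 ± 83.1 (1.42 ± 0.33, and 0.82 with equal totals). Summed per family, miR390 fell (-2.59 ± 0.22), as did miR395 (-2.19 ± 0.22, and -1.10 with quantile normalization), and the miR156 sum rose (2.07 ± 0.25).

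No list passed for 8106. In the SPL list 5 rose, 6 fell and 7 did not pass, in the auxin list 3 rose, 5 fell and 11 did not pass, in the growth list 14 rose, 17 fell and 30 did not pass, in the small RNA pathway list 1 rose, 0 fell and 2 did not pass, and in the copper list 2 rose, 2 fell and 3 did not pass. In the sulfur and phosphate list 0 rose, 2 fell and 5 did not pass, in the NB-LRR list 2 rose, 4 fell and 9 did not pass, in the legume list 3 rose, 6 fell and 17 did not pass, in the Arachis list 1 rose, 1 fell and 4 did not pass, and in the conserved core list 25 rose, 32 fell and 61 did not pass. Adjusted over the list alone, growth had 16 and 20 and conserved core 27 and 35, with the other counts as given. With equal totals 2 rose and 26 fell in the growth list, 0 and 12 in the legume list and 9 and 46 in the conserved core list. It was 1 and 7 in auxin and 0 and 4 in sulfur and phosphate. More rose than fell with median centring in growth (14 and 12), conserved core (26 and 24) and SPL (5 and 4). The same held with quantile normalization (14 and 13, 26 and 25, and 6 and 4). Median, mean and test differed in sign for the SPL, auxin, growth, NB-LRR, legume and conserved core lists. Of the 395 entries, 143 passed, 52 rose and 91 fell, with 176 (44.6%) not overlapping, and 6 fragment-like entries rose and 0 fell. The share that rose, 36.4%, was 15.6% with equal totals (24 rose and 130 fell). The median of all entries moved from -0.24 to -0.78 with equal totals, 0.12 with quantile normalization and -0.04 with median centring.

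In 8107, 6 of the 7 entries of the copper and laccase list fell between 15 and 35 DAF, all but gma-miR4376-5p_R-1_2ss16AG21GA. mtr-miR398b fell from 1789 ± 551 to 97.6 ± 19.6 (n = 3 each; -4.16 ± 0.27, limma adjusted p = 1.55e-06), and mtr-miR397-5p from 152 ± 64.2 to 13.8 ± 0.575 (-3.30 ± 0.31). ahy-miR3508 fell from 4428 ± 526 to 311 ± 63.8 (-3.84 ± 0.21). mtr-miR156e rose from 1535 ± 181 to 5764 ± 962 (1.90 ± 0.22), and mdm-miR156a_1ss11GA by 1.55 ± 0.32. mtr-miR172d-3p_R+1 did not pass, at 3167 ± 404 and 2832 ± 437. mtr-miR160a fell (-1.50 ± 0.21) and, summed per family, miR164 fell (-2.86 ± 0.22) as did miR171 (-1.32 ± 0.20), the last a call lost with quantile normalization (-0.58). ahy-miR408-3p fell from 30.9, 44.5 and 37.4 in the 3 libraries to a group listed at 0, and ahy-miR167-3p_L-1 rose from 1299.6 ± 166 to 8059.7 ± 885 (2.63 ± 0.16). mdm-miR482a-5p_L-1_2ss11TG20AT, from the other strand of miR482, rose by 4.59 ± 0.25, while gma-miR482b-3p fell (-1.23 ± 0.20).

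In the SPL and phase change list 10 rose, 0 fell and 8 did not pass (adjusted over the list alone, 10 and 0), with a median of 1.40 (camera adjusted p = 0.00666), and adjusted p = 0.934 with an estimated correlation. In the copper and laccase list 0 rose, 6 fell and 1 did not pass (0 and 6 adjusted over the list alone), with a median of -4.16 (camera adjusted p = 0.0177), and adjusted p = 0.934 with an estimated correlation. No other list passed. In the auxin list 6 rose, 3 fell and 10 did not pass, in the growth list 10 rose, 24 fell and 27 did not pass, in the small RNA pathway list 0 rose, 1 fell and 2 did not pass, in the sulfur and phosphate list 2 rose, 0 fell and 5 did not pass, in the NB-LRR list 2 rose, 5 fell and 8 did not pass, in the legume list 2 rose, 7 fell and 17 did not pass, in the Arachis list 2 rose, 1 fell and 3 did not pass, and in the conserved core list 29 rose, 36 fell and 53 did not pass. Only the legume counts differed adjusted over the list alone (2 and 6). With equal totals the majority turned, to 16 that rose and 14 that fell in growth and 41 and 24 in conserved core, where median centring gave 29 and 29. The signs of the small RNA pathway list's median, mean and test differed. Of 395 entries, 183 passed, 91 rose and 92 fell, with 229 (58%) not overlapping, and 4 fragment-like entries rose and 5 fell. The share that rose, 49.7%, was 64.1% with equal totals (125 rose and 70 fell), which moved the median of all entries from 0.06 to 0.42.

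The stage change differed between the lines for ahy-miR167-3p_L-1, with a difference of 4.78 ± 0.22 log2 units (limma adjusted p = 1.76e-07), since it fell in 8106 and rose in 8107. PC-5p-362_10574 fell in 8106 from 1585 ± 127 to 136 ± 11.6 and stood at 750.0 ± 90.5 and 1434 ± 58.7 in 8107 (4.47 ± 0.16, adjusted p = 3.55e-08). mtr-miR172d-3p_R+1 and mtr-miR172c-5p differed by 1.57 ± 0.20 and 3.42 ± 0.20, and mdm-miR156a_1ss11GA by 4.26 ± 0.45. The miR156 sum, however, rose in both lines, by 2.07 ± 0.25 in 8106 and 1.74 ± 0.25 in 8107. The degradome symbols of mtr-miR172c-5p were PRH and U2AF65B, not AP2-like factors. Differences were negative for ahy-miR398_R+1 (-2.96 ± 0.46), ahy-miR3508 (-2.86 ± 0.30) and, summed per family, miR164 (-2.30 ± 0.32) and miR171 (-1.63 ± 0.29), with -1.36 and -0.69 under equal totals. With equal totals mtr-miR172d-3p_R+1 was 2.51. For gma-miR482b-3p the difference was -1.73 ± 0.28, a call lost with equal totals. mtr-miR397-5p, listed at 0 in 8106 at 35 DAF, did not pass, and the sign of its difference depends on the constant added before the log.

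Of the lists, none passed for the difference of stage changes. The copper and laccase list had 0 higher, 4 lower and 3 not passed (median -2.96, and -1.92 without replicate 1 of 8106 at 15 DAF; adjusted p = 0.0743), and the SPL list 7 higher, 1 lower and 10 not passed (median 1.73, adjusted p = 0.0996). The auxin list had 7 higher, 2 lower and 10 not passed, the growth list 14 higher, 23 lower and 24 not passed, the small RNA pathway list 0 higher, 0 lower and 3 not passed, and the sulfur and phosphate list 3 higher, 0 lower and 4 not passed. The NB-LRR list had 3 higher, 5 lower and 7 not passed, the legume list 4 higher, 12 lower and 10 not passed, the Arachis list 1 higher, 2 lower and 3 not passed, and the conserved core list 32 higher, 31 lower and 55 not passed. Counts adjusted over the list alone differed for SPL (9 and 1), growth (16 and 23), legume (4 and 13) and conserved core (36 and 31). The SPL list had 14 higher and 1 lower with equal totals (median 2.54) and 5 and 1 with quantile normalization (1.18). Auxin had 11 and 0, and 3 and 1, and sulfur and phosphate 6 and 0, and 1 and 0. With equal totals the majority turned to 26 higher and 6 lower in growth, 8 and 1 in legume and 5 and 1 in NB-LRR. Conserved core had 60 and 11, against 22 and 31 with quantile normalization and 27 and 29 with median centring. Median, mean and test differed in sign for growth, NB-LRR, Arachis and conserved core. Of 395 entries, 162 passed, 88 higher and 74 lower, and the fragment-like entries had 2 higher and 7 lower. The share of higher calls, 54.3%, was 84% with equal totals (168 and 32) and 44.7% with quantile normalization (63 and 78), and the median of all entries moved from 0.52 to 1.40, 0.10 with quantile normalization and 0.36 with median centring.

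The line differences at the 2 stages share no libraries. Across the 395 entries, which are not independent replicates, they correlated at Pearson r = 0.319 and Spearman rho = 0.207, and 30 entries were higher in 8107 at both stages, where independent lists would give 19.9, and 9 lower at both (5.47). Another 12 were higher at 15 DAF and lower at 35 DAF and 8 the reverse. For the stage changes of the 2 lines, r was 0.152 and rho 0.104, with 16 entries that rose in both (11.98 if independent) and 33 that fell in both (21.2), while 14 rose in 8106 and fell in 8107 and 19 did the reverse.

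By length, 21 nt sequences took 60.01 ± 5.20% of normalized reads in 8106 at 15 DAF, 65.98 ± 8.50% at 35 DAF, 69.9 ± 4.57% in 8107 at 15 DAF and 75.5 ± 4.88% at 35 DAF (mean ± SD, n = 3 libraries). These shares are over the 795 listed entries, which are known or predicted miRNAs and hairpin arms. They are not shares of all small RNA reads and do not give the 24 nt content of the libraries. The 22 nt share, which holds miR482 and other triggers of phased small RNAs, was 37.7 ± 4.85% and 32.2 ± 8.10% in 8106 and 27.1 ± 4.74% and 18.7 ± 4.32% in 8107. The miR482 sum alone stood at 233745 and 307833 normalized reads in 8106 and 151209 and 71687 in 8107. Library totals were 464658 to 1086380. The 22 nt difference between lines may thus rest largely on miR482 and is not shown for the class as a whole. The 20 nt share was 0.754 ± 0.102% and 0.429 ± 0.154% in 8106 and 1.24 ± 0.205% and 3.08 ± 0.484% in 8107. The 24 nt share was 0.806 ± 0.349%, 0.645 ± 0.547%, 0.526 ± 0.223% and 1.68 ± 0.871% in the same order. With 3 against 3 libraries a two-sided exact permutation test can give no p under 0.1, and over 16 comparisons no adjusted p was under 0.229, so none could pass. The 20 nt shares of all 4 comparisons, the 22 nt shares between lines at both stages and the 21 nt share between lines at 15 DAF had groups that did not overlap. Pairs by replicate number were taken in the 3 comparisons where the rule set beforehand pairs the libraries, which a shared replicate 2 effect alone could give. All 3 pairs also went 1 way in 8107 from 15 to 35 DAF for the 21 nt share (7.45, 6.02 and 3.32 points), the 22 nt share (-10.3, -7.99 and -6.83) and the 24 nt share (1.10, 0.436 and 1.91). Between lines at 15 DAF they did so for the 24 nt share (-0.400, -0.150 and -0.288). An exact sign-flip test of 3 pairs can give no p under 0.25. With known names alone the mean 24 nt difference in 8107 was 0.106 points against 1.15, between lines at 35 DAF 0.0948 against 1.03, and at 15 DAF -0.00390 against -0.279.

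**Figure D3:**
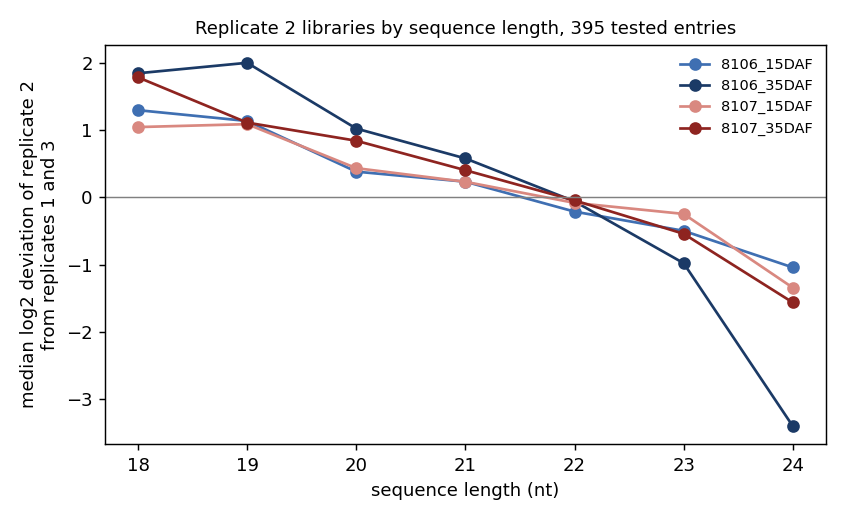
Median log2 deviation of replicate 2 from the mean of replicates 1 and 3, over tested entries, against sequence length from 18 to 24 nt, with a line for each of the 4 groups. The lines run from 1.30, 1.85, 1.05 and 1.79 at 18 nt to -1.04, -3.40, -1.34 and -1.56 at 24 nt in 8106 at 15 and 35 DAF and 8107 at 15 and 35 DAF.

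In the degradome, where the authors' table lists cleaved transcripts, the best-scoring targets of several conserved families belonged to their known classes. mtr-miR156e had SPL18 at a score of 0, mtr-miR159b had GAM1, a GAMYB-like factor, mtr-miR164a_R-3 had NAC100, and mtr-miR1507-3p_R-3 had RPPL1, an NB-LRR gene, each at 0 and each listed 2 times. mtr-miR160a had ARF17 at 0.5, and mtr-miR172d-3p_R+1 had AP2 at 1. By median score the known class did worse than the family's other combinations for miR396 (4 against 3) and miR167 (4 against 3.5). It did better in the other families of the 21 below that had both. Of 21 families with a known target class, chosen after the table was seen as families with symbols of that class, 1070 combinations fell in that class, of which 790 (73.8%) were listed 2 times, against 186 of 590 other combinations (31.5%). Combinations are not independent, since isoforms of a family share transcripts: miR156, with 20 small RNAs, had 323 class combinations on 28 transcripts. Over all families the median score was 3 for combinations listed 2 times and 4 for those listed 1 time. miR397 and miR398 had no symbol of their classes (laccases and copper superoxide dismutases) in 6 and 10 combinations, and miR169 no NF-YA symbol in 27, all of hairpin arms. With these 3 families the others were 192 of 633 (30.3%). The share listed 2 times was 100% for miR164 (NAC), miR171 (SCL6) and miR393 (auxin receptors), 95.4% for miR166 and 96.4% for miR167, but 0% for miR482, miR1510, miR828 and miR408. The class share against that of the family's other combinations was 58.7 against 72.2% for miR159, 25 against 35.5% for miR1515, 0 against 42.9% for miR408 and 0 against 18.9% for miR482, differences that were not tested.

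The table held 2497 combinations of small RNA, transcript and site, 1133 of them listed 2 times (45.4%), from 257 small RNAs and 1196 transcripts, with 328 symbols and 397 combinations without one. Transcripts were listed for 42 of the 89 entries that passed between lines at 15 DAF, 97 of 207 at 35 DAF, 62 of 143 and 79 of 183 that changed in 8106 and 8107, and 80 of 162 whose change differed. There was 1 degradome library per line and no column naming it, so no test of a difference between lines was run.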

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

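The 28 entries here were picked out because the change from 15 to 35 DAF differed between the lines by a test of that difference (limma, adjusted p under 0.05), given as the log2 change in 8107 minus that in 8106. For the copper pattern, both tests were chosen after the result had been seen.

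In the copper and laccase list, the difference was -2.96 for ahy-miR398_R+1, -2.52 for mtr-miR398b and -1.43 for gma-miR4376-5p_R-1_2ss16AG21GA, of a family known for a calcium ATPase target, the last a call lost with equal library totals. Of families with auxin targets it was 4.78 for ahy-miR167-3p_L-1, -1.08 for ahy-miR167-5p and -1.27 for mtr-miR160a, the last 2 lost with equal library totals. Of the miR156 and miR172 families, mdm-miR156a_1ss11GA had 4.26, mtr-miR172d-3p_R+1 1.57 and mtr-miR172c-5p 3.42. The miR156 sum rose in both lines (2.07 in 8106 and 1.74 in 8107), so the value of mdm-miR156a_1ss11GA does not stand for its family. Of miR166, mtr-miR166e-5p_2ss10GT11CT had 4.92, mtr-miR166a_1ss20CT -1.75 and mtr-miR166a -0.93, which turned positive with equal library totals. Of miR395, mtr-miR395a_L+1R-1_1ss21TC had 2.27 and mtr-miR395a_L-1R+1_1ss21CT 1.88, the last lost with quantile normalization.

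Of the families with NB-LRR targets, the difference was -1.73 for gma-miR482b-3p, -1.40 for mtr-miR2118_2ss3AG18TG and -1.18 for mtr-miR1507-3p_L+1R-1, all lost with equal library totals. The identical entries gma-miR1511_R+1_1, gma-miR1511_R+1_2 and gma-miR1511_R+1_3 each had -1.18, also lost with equal library totals and with quantile normalization, as was mtr-miR2118_2ss3AG18TG. Of the families registered in Arachis, ahy-miR3508 had -2.86, ahy-miR3514-3p 1.75 and ahy-miR3518 -1.02, the last lost with equal library totals. The predicted candidate PC-5p-362_10574 had 4.47. PC-3p-23476_334 (8.70), mtr-miR2199_1ss17AG (8.30), PC-3p-8612_823 (4.93) and mtr-MIR167a-p3_1ss14TC (5.16) were listed at 0 in all libraries of 8106 at 35 DAF, so their values depend on the added constant and are no bound.

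The copper and laccase list, higher in 8107 at 15 DAF, was weighed against 2 technical explanations. The lowest median log2 difference over 3 other scalings was 2.89, and the lowest over the 6 leave-outs 2.71, so neither the scaling nor 1 library accounts for it. A difference between the lines in copper supply or copper response in young seeds is a hypothesis that these values leave open, and the list's call was lost with an estimated correlation. Copper content is not analysed here, so this was not tested.

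Chance as the source of the counts was tested by splitting the libraries of each comparison in other ways. For the 4 comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real counts were 89, 207, 143 and 183, and the highest of the others 1, 2, 2 and 1. Every other split mixes both groups on each side, where a difference between groups adds to the spread. Low counts there thus follow from the pattern itself and cannot exclude chance. For the difference of stage changes the real count of 162 was the highest of 100 splits, with a highest other count of 121. These splits exchanged line labels within each stage, which also removes the line differences. They therefore cannot exclude chance as the source of the difference of stage changes itself.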

How the results depend on the processing

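Of 7098 recomputed values of 259 named results, 6676 kept direction and side of the threshold, 265 became weaker, 135 stronger and 22 reversed. The cause of changes below was not tested unless stated. Depth limits the low entries, since values under about 6 reads are listed at 0.

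Fewer entries are tested with known entries alone, where counts were 47 and 111 for the lines at 15 and 35 DAF, 80 and 88 for the stage in 8106 and 8107 and 99 for the difference of stage changes, and with sums per family, where they were 11, 29, 20, 24 and 25. A minimum of 50 in 3 libraries gave 134 at 35 DAF and 118 for the stage in 8107. At 15 DAF the replicate block gave 145 and voom with sample quality weights 170. Only the 6 libraries compared gave 137 at 35 DAF, and this setting does not apply to the difference of stage changes. Leaving out 1 library at a time gave 42 to 112 at 15 DAF, 171 to 211 at 35 DAF, 117 to 147 in 8106, 148 to 205 in 8107 and 140 to 173 for the difference. With the replicate block the other counts were 253 at 35 DAF, 172 in 8106, 230 in 8107 and 210 for the difference. Of 259 named results, 21 gained a call under the block and 0 lost one, and no list call changed. Without the 4 replicate 2 libraries, a setting chosen after seeing the data, counts were 111, 224, 152, 205 and 182, and at 15 DAF 66 entries were higher and 45 lower (59.5% higher). Without fragment-like entries they were 82, 199, 137, 173 and 152.

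Of 3 list calls, 0 remained with an estimated correlation, fry gave 19 and hairpin arms included gave 6, which added growth (adjusted p = 0.0172) and conserved core (0.00591) at 15 DAF and copper for the difference of stage changes (0.0178).

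With quantile normalization, values reversed for mtr-miR166a to 0.63 at 35 DAF, 0.45 in 8107 and 0.28 for the difference of stage changes, which follow from its rank of 2 to 4 in all libraries, and for gma-miR168a to 0.0242 at 35 DAF and 0.64 for the difference. With equal library totals, chosen after seeing the data, line differences at 35 DAF turned to 0.65 for mtr-miR156e, 0.0742 for mtr-miR160a, 0.83 for gma-miR167c_L+1_1ss22GT, 0.58 for mtr-miR166a, 0.61 for mtr-miR159a_1ss21AT, 0.27 for gma-miR168a, 0.92 for gma-miR162a_R+1, 0.31 for mtr-miR398b, 0.64 for gma-miR4376-5p_R-1_2ss16AG21GA, 0.0509 for mtr-miR1507-3p_L+1R-1, 0.25 for each of gma-miR1511_R+1_1, gma-miR1511_R+1_2 and gma-miR1511_R+1_3, and 0.59 for ahy-miR3518. mtr-miR166a turned to -0.0615 in 8106 and 0.00902 for the difference of stage changes. With a pseudocount of 10, mtr-miR397-5p turned to -1.15 for that difference.

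The difference of 24 nt shares with known names alone moved to 0.0948 points between lines at 35 DAF and 0.106 from 15 to 35 DAF in 8107. Of degradome combinations 1131 of 2493 pairs were listed 2 times, against 335 of 545 at a score of 2.5 or less, 393 of 1196 by transcript and 383 of 1094 by family and transcript, each with fewer units. Degradome categories and p thresholds were not run, since the table has neither.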

Other observations

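ahy-MIR3511-p5 and ahy-MIR3516-p5, arms of hairpins registered in Arachis, had degradome targets among DNA demethylases, which remove methylated cytosine. ahy-MIR3511-p5 matched ROS1 and DML2 at a score of 0, listed 2 times, and ahy-MIR3516-p5 matched ROS1 at 0, listed 1 time. ahy-MIR3511-p5 was listed at 5.65, 11.4 and 0 in the 3 libraries of 8106 at 35 DAF and 154, 210.4 and 136 in 8107 (5.24 ± 1.05, limma adjusted p = 0.00196), and at 0, 12.5 and 10.1 and 44.6, 61.6 and 62.8 at 15 DAF (3.42 ± 1.05). ahy-MIR3516-p5 was listed at 6.46, 8.04 and 0 in 8106 and 2964, 3667 and 2658 in 8107 at 35 DAF (9.56 ± 0.67, adjusted p = 7.83e-07). These pairs and those below were chosen after the table had been seen.

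The predicted candidate PC-3p-8612_823 (CTATTGAGCCGTGCCAATATC) had 4 transcripts of SCL6, a SCARECROW-like factor, at a score of 4. It stood at 72.9 ± 4.04 in 8107 at 35 DAF and was listed at 0 in 8106 at that stage. The miR171 family also had 4 transcripts of SCL6, so PC-3p-8612_823 may be a form of miR171 and cannot count as a separate regulator. Summed per family, miR171 was lower in 8107 at 35 DAF (-1.10 ± 0.20), a call lost with equal totals. PC-3p-231_14884 (TTTCATTCCATACATCATCTAT) had 37 transcripts of the NB-LRR genes RGA1, RGA2, RGA3 and RPPL1, and stood at 2294 ± 232 in 8107 and 809 ± 124 in 8106 at 35 DAF (1.51 ± 0.14, adjusted p = 8.03e-06). PC-3p-231_14884 shared an RGA3 cleavage site with gma-MIR1507b-p3_2ss2CT17GA, so its targets overlap those of miR1507. Isoforms of miR164a matched UXS6, an enzyme of UDP-xylose synthesis, at scores of 2 and 3.5. An isoform of miR1511 matched OLE9, an oleosin, at 3, and PC-3p-35835_224 matched KAO1 and KAO2, enzymes of gibberellin synthesis, at 4, each listed 2 times.

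The replicate 2 libraries of the 4 groups deviated together from their group means, and the tests for this pattern were chosen after it had been seen. Sequence length and deviation correlated at Spearman rho = -0.699 in the group with the smallest absolute value, where entries are not independent replicates, so a length bias of these libraries, as from gel selection, fits. For end trimming, the smallest absolute median deviation of shortened minus extended entries was 0.308, and this cannot be told. In 3 groups replicate 2 had more reads than another replicate, so lower depth is excluded, a prediction written after the values were known. No biological explanation was tested.

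The tests of the line-restricted entries were also chosen after the result had been seen. PC-3p-4234_1541 and PC-5p-34874_230 were the only 2 entries listed at 0 in all 6 libraries of one line and at 10 or more in all 6 of the other, both in 8107. None of them had a near-identical partner (0 entries), listed within 1 base difference and an end shift of up to 2 and at least 4-fold higher in 8106. Reads moved to such a partner are thus excluded, but not reads moved to a sequence with more differences or one not listed. The median of their means in 8107 was 225, against 4.81 for the highest of the libraries' lowest listed values. Low depth is excluded by this, a prediction written after the values were known. Of 100 splits only 1, the real one, had as many entries (highest other 0). Every other split mixes libraries of both lines on each side, where these 2 entries cannot qualify. The splits thus restate the pattern that prompted them and cannot exclude chance. As arms of 1 hairpin their duplex energy was -19.8 kcal per mol, rank 2 of 794. That rank cannot tell whether 1 locus, perhaps absent from 8106, accounts for both. The 2 sequences are complementary over most of their length, so they may be arms of 1 hairpin and cannot count as 2 independent entries.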
